A study of Mus musculus with 2 samples.

How the data were processed

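Mouse pancreatic islets of a db/db and a db/m group were profiled by RNA sequencing, and 2 libraries were analysed here, 1 per group. Per the labels' protocols, islets were isolated with collagenase and a density gradient, total RNA was extracted directly and ribosomal RNA was removed before library construction. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.4 and the genome builds named are mm10 and GRCm38. The counting program, its annotation, the use of strand and the treatment of reads that match several places are not given in the sources used here. The deposited table holds whole-number counts per gene, made by the authors, with a gene symbol and a gene class per line, and 1 column of counts per library. It lists 44713 genes without duplicated names, of which 18886 had a count in either library. The series describes triplicates, but 1 library per group was analysed here, and nothing in the labels says how many animals gave the islets of a library.

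The groups were taken from the library titles and genotype labels. The totals were 18233695 counts for the db/db library and 16271129 for the db/m library. The counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 and divided by the scaled library size, which gave CPM. Each gene's ratio of db/db over db/m has an exact 95% counting interval, obtained with the Clopper-Pearson method from the db/db share of the 2 counts and converted with the scaled library sizes (Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). A gene was called higher or lower when the ratio was at least 2-fold, the mean unscaled CPM at least 1 and the interval excluded 1, which left 10300 genes to compare. No p-value was computed, because 1 library per group leaves no replicate error. Reads copied by PCR are not independent molecules, so the intervals cover counting error only and describe these 2 libraries, not the genotypes. Where a gene had 0 counts in a library, a floor of 3 counts was used for the log2 ratio and for any lower bound on a fold. Where the other library had fewer than 3 counts, that count was the floor, or 1 if it was 0 too. Genes with 0 against at most 3 counts, or with equal counts, so have a log2 ratio of -0.34 that the scaled library sizes alone set. Shares of counts have exact binomial intervals.

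The scripts were tested on simulated data for the comparison of db/db against db/m, in which counts were drawn for all 44713 genes and 200 were given known fold changes. Among 10272 genes tested there, all genes raised 8-fold or 3-fold were called (100%), as were 87.5% of those lowered to 0.333 and 85% of those lowered to 0.125 of their level. Of the genes raised 1.5-fold, 0% were called, and 39 unchanged genes were called. These simulated counts held counting error only and were compared with the library sizes given. The 39 calls are therefore no error rate for libraries of different animals, and the TMM scaling was not tested. The intervals held the true fold for 90% to 97.5% of the genes at each fold.

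Before the data were examined, 31 gene lists were fixed, together with the calling rule, the alternatives and the rule for genes to be named. The lists cover islet hormones and granule proteins, beta cell transcription factors, glucose sensing, genes silent in beta cells, dedifferentiation, markers of 11 cell types, stress, metabolic, immune, immediate early and Reg genes, named long non-coding RNAs, sex-linked genes and transcripts without a poly(A) tail. Of their 723 entries, 697 were found in the table. The median log2 ratio of the members with at least 1 CPM was set among the medians of 10000 random lists of the same size, drawn with seed 1 from genes in the same of 20 expression bins. The percentile describes these libraries and is not a test between genotypes. Counting intervals of list medians came from redrawing the counts. The named genes are Lepr, the 7 hormone genes, the 12 genes highest and the 12 lowest by the interval bound nearest to 1 among genes with at least 10 CPM and no clone-type name, up to 4 members of each list with at least 10 CPM and the largest log2 ratio, the 5 highest and 5 lowest non-coding RNAs of a class, and the 5 most abundant genes of each library. Genes named outside this rule were chosen after their values were seen. Gene positions come from the RefSeq annotation of GRCm38.p6, matched by symbol for 98% of the compared genes (10096). Figures were drawn with matplotlib 3.10.9. Some genes that entered the counts and medians are not reported here by name.

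The alternatives were scaling by total counts, by DESeq2 1.42.0 size factors and by total counts without hormone and acinar genes, no filter or a filter of 10 CPM on low counts, fold limits of 1.5 and 4, an interval lying beyond 2-fold, an interval at the Bonferroni level, lists without members that stand on another list, and hormone shares without acinar or mitochondrially encoded genes. Added after the data were seen were the comparison against Ins2, the class marked ncRNA, the counts without trypsinogen, immediate early and heat shock genes, and further lists of heat shock genes, clock genes, glucocorticoid targets and trypsinogen genes.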

Results

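Gene counts from RNA sequencing were analysed for pancreatic islets of 2 groups of mice, with 1 library in each group. The db/db library came from mice lacking a functional leptin receptor (labelled Lepr-/-), a widely used model of obesity and type 2 diabetes, and the db/m library, given as wild type in the labels, was its control. Per the labels, the islets had been freed from the pancreas with collagenase and purified on a density gradient, and ribosomal RNA had been removed from the total RNA, so that transcripts without a poly(A) tail could also be read. The db/db library held 18233695 counts over 17242 detected genes and the db/m library 16271129 counts over 16930 detected genes. After scaling, 1 count stood for 0.0516 CPM (counts scaled to the size of the library) in the db/db library and 0.0653 CPM in the db/m library. With 1 library per group no difference has a replicate check, no p-value is given, and each ratio carries a 95% interval for counting error alone.

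The comparison asked which messenger RNAs and long non-coding RNAs differ between islets of diabetic and control mice. Hormone transcripts of the delta, PP and alpha cells of the islet were higher in the db/db library, by 8.79-fold for somatostatin (Sst, 95% interval 6.81 to 11.5), 6.44-fold for pancreatic polypeptide (Ppy, 5.25 to 7.98) and 3.99-fold for glucagon (Gcg, 3.68 to 4.32). The insulin genes of beta cells differed less, with Ins2 at 1.05-fold (1.03 to 1.07) and Ins1 2.11-fold lower (2.01 to 2.22). Immediate early genes, a group of 9 heat shock genes chosen after their values were seen, the Reg family of secreted lectins and the genes encoded by the mitochondrial genome were lower in the db/db library, with Hspa1b 35.6-fold (30.5 to 41.8), Jun 16.4-fold (14.6 to 18.5), Reg2 15.6-fold (15.1 to 16.1) and ND2 4.27-fold (3.9 to 4.67) below the db/m library. Of 10300 genes with a mean of at least 1 CPM, 395 were at least 2-fold higher and 416 at least 2-fold lower in the db/db library with an interval excluding 1, together 7.87% of the genes compared. Across these genes the CPM of the libraries had a Spearman rho of 0.951, a description in which genes are not independent replicates. The balance of higher and lower calls depended on the scaling, since 48.7% of calls were higher with the trimmed mean of M values (TMM) and 67.1% with total counts (564 higher, 277 lower), under which every log2 ratio was larger by 0.175.

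**Figure D1:**
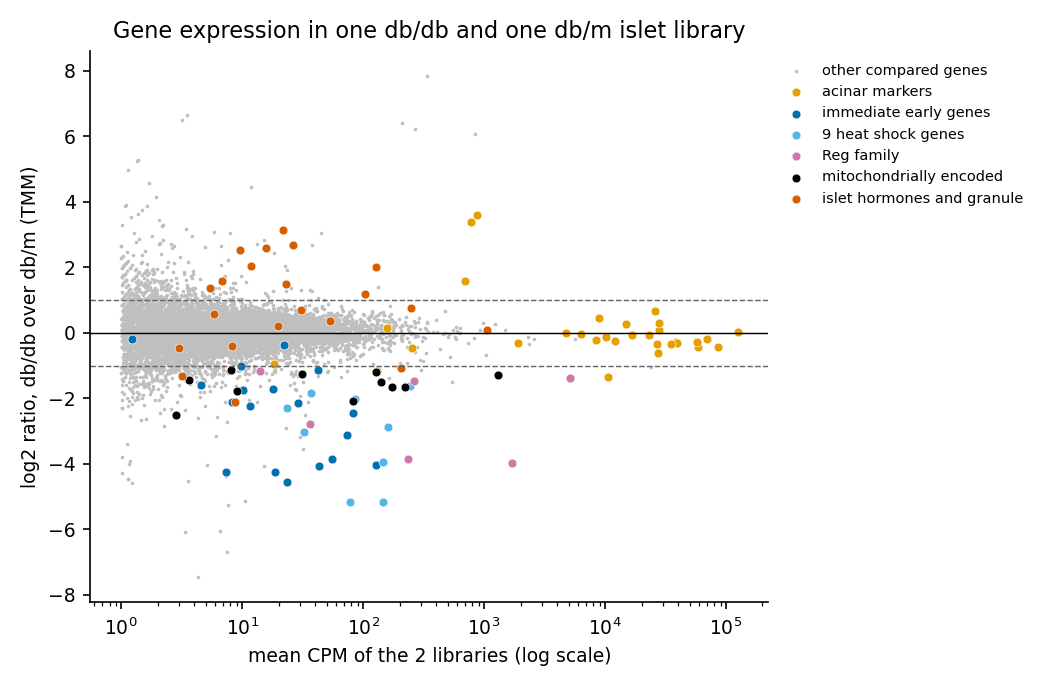
Each point is 1 of the 10300 genes compared, with the mean CPM of the 2 libraries on the x axis (log scale), the log2 ratio of db/db over db/m after TMM scaling on the y axis and dashed lines at 2-fold. Acinar markers fill the most abundant genes near a ratio of 0, while immediate early, heat shock, Reg and mitochondrially encoded genes lie below it and most islet hormone and granule genes above it.

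Lepr, the leptin receptor gene named in the genotype label (chromosome 4, 101717137 to 101815352 in GRCm38), had 3 counts in the db/db library and 4 in the db/m library. The ratio of 0.593 had an interval of 0.0868 to 3.5, so no difference was detectable at this depth. The db mutation alters the splicing of one isoform, and a count over the whole gene does not check the label.

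Genes of the exocrine pancreas made up most of both libraries, which the labels give as islet cells by source and pancreas by tissue. The 32 measured acinar markers, which encode digestive enzymes and other acinar cell products, took 76.8% of the db/db counts (95% exact binomial interval 76.76% to 76.79%) and 77.3% of the db/m counts (77.28% to 77.32%). Chymotrypsinogen (Ctrb1), pancreatic lipase (Pnlip), carboxypeptidases Cpa1 and Cpb1 and elastase Cela2a were the 5 most abundant genes in both libraries and took 38.9% and 40.2% of the counts. Ctrb1 alone stood at 125200 CPM in the db/db library and 123200 CPM in the db/m library. Of the acinar markers, 3 were higher in the db/db library (Prss1, Prss3 and Try10), 3 were lower (Amy2a5, Amy2b and Reg1) and 26 were neither. Their median log2 ratio was -0.20, at percentile 0.03 of 10000 random lists matched on expression, while their mean was 0.03. With total counts the median was -0.03. The 7 islet hormone genes Ins1, Ins2, Iapp, Gcg, Sst, Ppy and Pyy together took 0.193% of the db/db counts (0.191% to 0.195%) and 0.147% of the db/m counts (0.145% to 0.149%). How pure the islets were is not given in the sources used here, and the ratios of genes that acinar cells express describe mostly acinar RNA.

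Among 21 measured hormone and secretory granule genes, 10 were higher in the db/db library, 3 lower and 8 neither. The median log2 ratio was 0.75 (counting interval 0.71 to 0.99), at percentile 100 of the random lists, and 0.58 without the 4 members that stand on another list. Peptide YY (Pyy) was 5.72-fold higher (4.13 to 8.1), the granule protein Chgb 5.96-fold (4.61 to 7.83) and the granule membrane protein Ptprn 4.11-fold (3.17 to 5.42). Islet amyloid polypeptide (Iapp), which beta cells release with insulin, was 1.69-fold higher (1.61 to 1.76), below the 2-fold limit. The 3 lower genes were Ins1, Slc30a8 (4.35-fold, 3.3 to 5.81), the zinc transporter of the insulin granule, and Ucn3 (2.5-fold, 1.65 to 3.84), and the last 2 were named after their values were seen. The call for Ins1 was lost with total counts, where its log2 ratio was -0.90. Alpha cell markers were higher in 4 of 9 cases (Gcg, Gc, Dpp4 and Gria3), lower in none, with a median log2 ratio of 0.78 at percentile 100. That median was -0.02 without the filter on low counts. Delta and PP cell markers were higher in 5 of 9 (Sst, Ppy, Pyy, Etv1 and Rbp4), lower in none, with a median of 1.09 at percentile 100, and 0.34 without the 3 members on another list. The summed counts of the alpha cell markers were 1.56-fold higher (1.49 to 1.62) and those of the delta and PP cell markers 2.83-fold higher (2.61 to 3.07). These sums were carried by the hormone genes, and without them, a setting added after the values were seen, the ratios were 0.882 (0.838 to 0.93) for alpha cells, in the other direction, and 1.25 (1.12 to 1.39) for delta and PP cells.

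**Figure D2:**
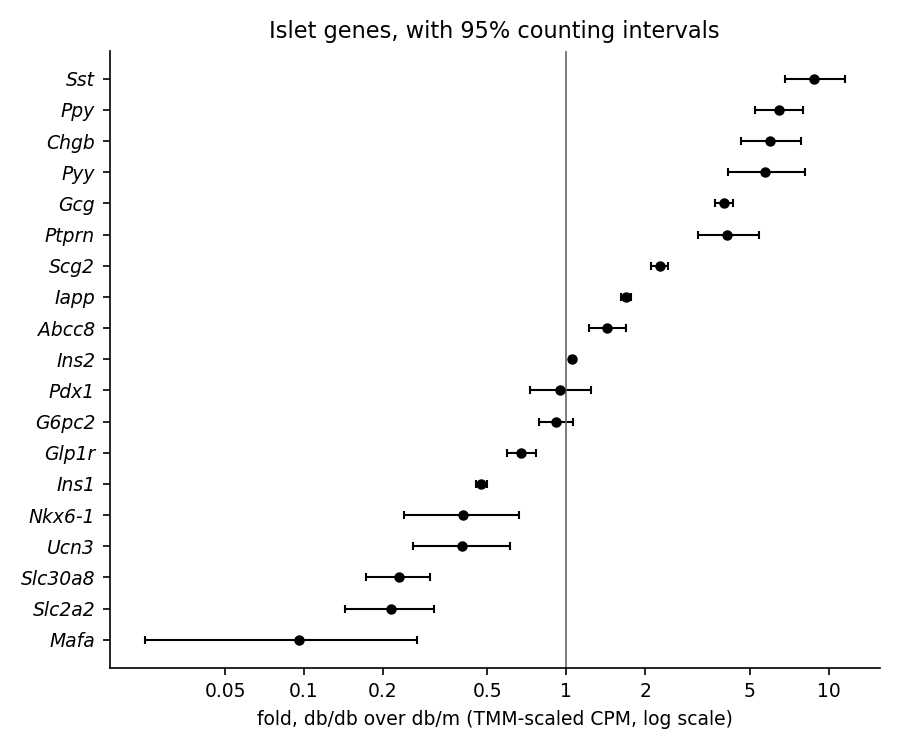
Fold of db/db over db/m after TMM scaling (x axis, log scale) for genes of the islet lists, several of them chosen after their values were seen, with points for the ratio of the 2 libraries and bars for the 95% counting interval. Sst lies at 8.79 and Ins2 at 1.05, and Mafa, with the lowest ratio, at 0.0958.

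Beta cell genes did not share one ratio. The list of beta cell transcription factors had 18 measured genes, not all of which are limited to beta cells. In the db/db library 2 were higher (Isl1 and Rfx6), 5 were lower (Mafa, Nkx6-1, Neurod1, Hnf4a and Glis3) and 11 were neither. Their median log2 ratio of -0.12, at percentile 14.1, was 0.06 with total counts. Hnf4a, a factor that acinar and duct cells also express, was 2.38-fold lower (2.08 to 2.73). Mafa, an activator of the insulin genes in mature beta cells, had 4 counts in the db/db library and 33 in the db/m library, a 10.4-fold difference (3.71 to 40.6), whereas Pdx1 was at 0.947-fold (0.726 to 1.24). In the list of glucose sensing and insulin secretion, 3 of 23 genes were higher (Kcnk16, Tmem27 and Snap25), 2 were lower (Slc2a2 and Stx1a) and 18 were neither, with a median of 0.12 at percentile 83.3 that was -0.11 among genes with at least 10 CPM. Slc2a2, the main glucose transporter of mouse beta cells, was 4.66-fold lower (3.19 to 6.98), and Tmem27 was 8.31-fold higher (5.51 to 13.1). The sulfonylurea receptor gene Abcc8 stood at 1.43-fold (1.22 to 1.68) and the receptor gene Glp1r was 1.48-fold lower (1.31 to 1.69), both within the 2-fold limit. Mafa, Pdx1, Slc2a2 and Tmem27 were named after their values were seen.

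Because Ins2 differed little between the libraries, 15 beta cell genes were also set against Ins2 within each library, a comparison added after the values were seen. With Ins2 at 1.05-fold, this step changed the ratios given above only slightly and is no separate support for them. Judged by the interval alone, 10 genes were lower in the db/db library on this scale, 8 of them at least 2-fold, 2 were higher (Iapp and Abcc8), 0 of them at least 2-fold, and 3 had an interval that includes 1, among them Pdx1 and G6pc2. Ins1 was 12.5% of Ins2 in the db/db library and 27.7% in the db/m library, a ratio of 0.451 (0.428 to 0.476). The ratio was 0.204 for Slc2a2 (0.136 to 0.299), 0.219 for Slc30a8 (0.164 to 0.289), 0.381 for Ucn3 (0.248 to 0.578) and 0.0912 for Mafa (0.0235 to 0.256). The ion channel gene Trpm5 had 0 counts in the db/db library and 18 in the db/m library.

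In the list of dedifferentiation and progenitor genes 2 of 5 measured members were higher in the db/db library, both named after their values were seen. Aldh1a3, a retinaldehyde dehydrogenase and marker of dedifferentiated beta cells, had 126 counts in the db/db library and 1 in the db/m library, a ratio of 99.6 (17.6 to 3960). Serpina7 had 60 counts against 2, a ratio of 23.7 (6.28 to 200). The other 3 members were neither, and the median of the list was -0.10 at percentile 31.2 while its mean was 2.02. That median gives the list no direction, since it was 4.57 without the 2 members on another list, 0.07 with total counts and -0.78 among genes with at least 10 CPM. Of 26 genes that mature beta cells normally keep silent, 1 was higher (Igfbp4), 3 were lower (Zfp36l1, Zyx and Arap2) and 22 were neither, with a median of -0.07 at percentile 11.8 that was 0.10 with total counts. Many genes of this list are active in other pancreatic cells.

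Immediate early genes, which respond within minutes to stimuli and to tissue handling, were lower in the db/db library in 16 of 18 cases, and the other 2, Myc and Dusp5, were neither. Their median log2 ratio was -2.19 (counting interval -2.43 to -2.05), below all 10000 random lists. Atf3 was 23.5-fold lower (17 to 33.3), Fosb 19.2-fold (13.9 to 27.5), Egr1 16.9-fold (13.8 to 21) and Fos 14.6-fold (12.3 to 17.4). A group of 9 heat shock genes, put together after these differences were seen, was lower throughout with a median of -2.87. Of 18 other targets of heat shock factor, 3 were lower (Dnaja1, Bag3 and Chordc1), 0 were higher and 15 were neither. Their median was -0.41 at percentile 0.02, and 15 of the 18 had a ratio below 1. The inducible chaperone genes Hspa1a and Hspa1b were 35.8-fold (28.9 to 44.9) and 35.6-fold lower, and the chaperone gene Hsph1 15.4-fold (13.8 to 17.2). Hspa1a and Hspa1b are near-identical neighbours on chromosome 17, so the split of reads between them is uncertain. Snord14d, which lies within Hspa8 on chromosome 9 (40803995 to 40804081), was 35.2-fold lower (19.9 to 68.8) beside a 3.1-fold difference of Hspa8 (2.96 to 3.26), which was named after its values were seen. Of 22 other genes that were over 8-fold lower, 8 lay within 30 kb of one of the 27 measured genes of these immediate early and heat shock groups, against 0.348% (35) of 10069 compared genes outside the groups, and among them were Fam71a near Atf3 and Gm8696 near Hspa1b. These 35 near genes as a whole were not lower, with a median log2 ratio of -0.04 against 0.03 for the rest. Mir207, not among the 8, had 0 counts against 38 and lies within Dnaja1 on chromosome 4. The strand used in counting is not given in the sources used here, so these neighbours are uncertain.

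The Reg family, secreted lectins of the exocrine pancreas and of stressed islets, was lower in the db/db library in all 6 measured members, with a median log2 ratio of -2.13 (counting interval -2.25 to -2.01) at percentile 0. Reg2 was at 215 CPM in the db/db library and 3363 CPM in the db/m library. Reg3b was 14.4-fold lower (13.2 to 15.6), Reg3a 6.96-fold (5.95 to 8.19), Reg3d 2.75-fold (2.63 to 2.88) and Reg1 2.58-fold (2.55 to 2.6). The family took 0.354% of the db/db counts and 1.11% of the db/m counts.

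Trypsinogen genes on chromosome 6 (40964772 to 41525079 in GRCm38) were higher in the db/db library in 8 of 12 cases and neither in 4. Prss3 was 12.1-fold higher (11.6 to 12.7), Prss1 10.4-fold (9.98 to 10.9) and Try10 2.98-fold (2.89 to 3.08), and Gm10334, named after its values were seen, had 12237 counts against 42. The 8 higher genes made up 5.93% of the trypsinogen counts in the db/db library and 0.517% in the db/m library. The abundant members stayed closer together, with Prss2 1.28-fold lower (1.27 to 1.28) and Try5 1.59-fold higher (1.58 to 1.6), both named after their values were seen. These copies are similar in sequence, and the values of single members are uncertain where counting could split reads between them.

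Genes encoded by the mitochondrial genome were lower in all 11 measured cases, with a median log2 ratio of -1.50 (counting interval -1.67 to -1.42) at percentile 0. ND2 stood at 32.6 CPM in the db/db library and 139 CPM in the db/m library, CYTB was 3.17-fold lower (3.01 to 3.33), ND4 3.13-fold (2.96 to 3.32) and ND5 2.83-fold (2.66 to 3.01). All 13 mitochondrially encoded genes took 0.126% of the db/db counts and 0.293% of the db/m counts. Their levels were uneven, with 15004 and 28842 counts for COX1 and 39 and 84 for COX2, both named after their values were seen, and since the nuclear genome holds copies of mitochondrial sequence and the treatment of shared reads is not given in the sources used here, these values are uncertain. Nuclear genes of oxidative phosphorylation showed no such difference, with 0 of 43 called in either direction and a median of -0.01 at percentile 24.9 that was 0.16 with total counts. Ndufs1 was at 1.48-fold (1.25 to 1.75) and Cox6c 1.53-fold lower (1.3 to 1.81).

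Among fatty acid oxidation genes and targets of the PPAR receptors, 3 of 22 were lower (Pdk4, Angptl4 and Acadl), 1 was higher (Ppargc1a) and 18 were neither, with a median of -0.42 at percentile 0. Pdk4, which restrains pyruvate oxidation, was 11.6-fold lower (9.48 to 14.4), and Acadl, an acyl-CoA dehydrogenase, 2.52-fold (2.19 to 2.9). Of 28 genes of lipid and cholesterol synthesis, 1 was higher (Scd2, 2.91-fold, 2.27 to 3.76), 0 were lower and 27 were neither, with a median of 0.19 at percentile 97.3. Of 20 glycolysis genes, 1 was higher (Pfkp), 1 was lower (Gapdh) and 18 were neither, with a median of 0.09 at percentile 70.4. Gapdh, which was named after its values were seen and has many processed pseudogenes, had 11 and 24 counts, and its value is uncertain. Of 8 measured cell cycle genes, 1 was lower (Tyms) and 7 were neither, with a median of 0.06 at percentile 59.7. Without the filter on low counts the median was -0.34, the value that genes with equal or floored counts receive. That median therefore shows no difference of these genes.

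In the list of the unfolded protein response, 25 of 32 genes had ratios above 1, with a median log2 ratio of 0.34 (counting interval 0.28 to 0.38) at percentile 100, although 28 members did not reach the 2-fold limit. The 1 higher gene was Trib3 (4.7-fold, 3.34 to 6.78), and the 3 lower genes were Atf3, Ppp1r15a (3.11-fold, 2.54 to 3.82) and Txnip (2.59-fold, 2.45 to 2.75), which binds thioredoxin. Xbp1, a central factor of the response, was 1.79-fold lower (1.72 to 1.86), Herpud1 was at 1.6-fold (1.55 to 1.65) and the chaperone gene Hspa5 at 0.983-fold (0.953 to 1.01). Trib3, Herpud1 and Hspa5 were named after their values were seen. The antioxidant list had 1 higher gene (Gpx3), 1 lower gene (Gclc, 3.05-fold, 2.62 to 3.55) and 18 others, with a median of -0.15 at percentile 2.45 that was 0.03 with total counts. Of 9 inflammatory and NF-kB target genes, 3 were lower (Socs3, Tlr2 and Nfkbia), 0 were higher and 6 were neither, with a median of -0.66 at percentile 0.07. None of 8 interferon response genes was called in either direction, and their median of -0.16 at percentile 16.6 was 0.02 with total counts.

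**Figure D3:**
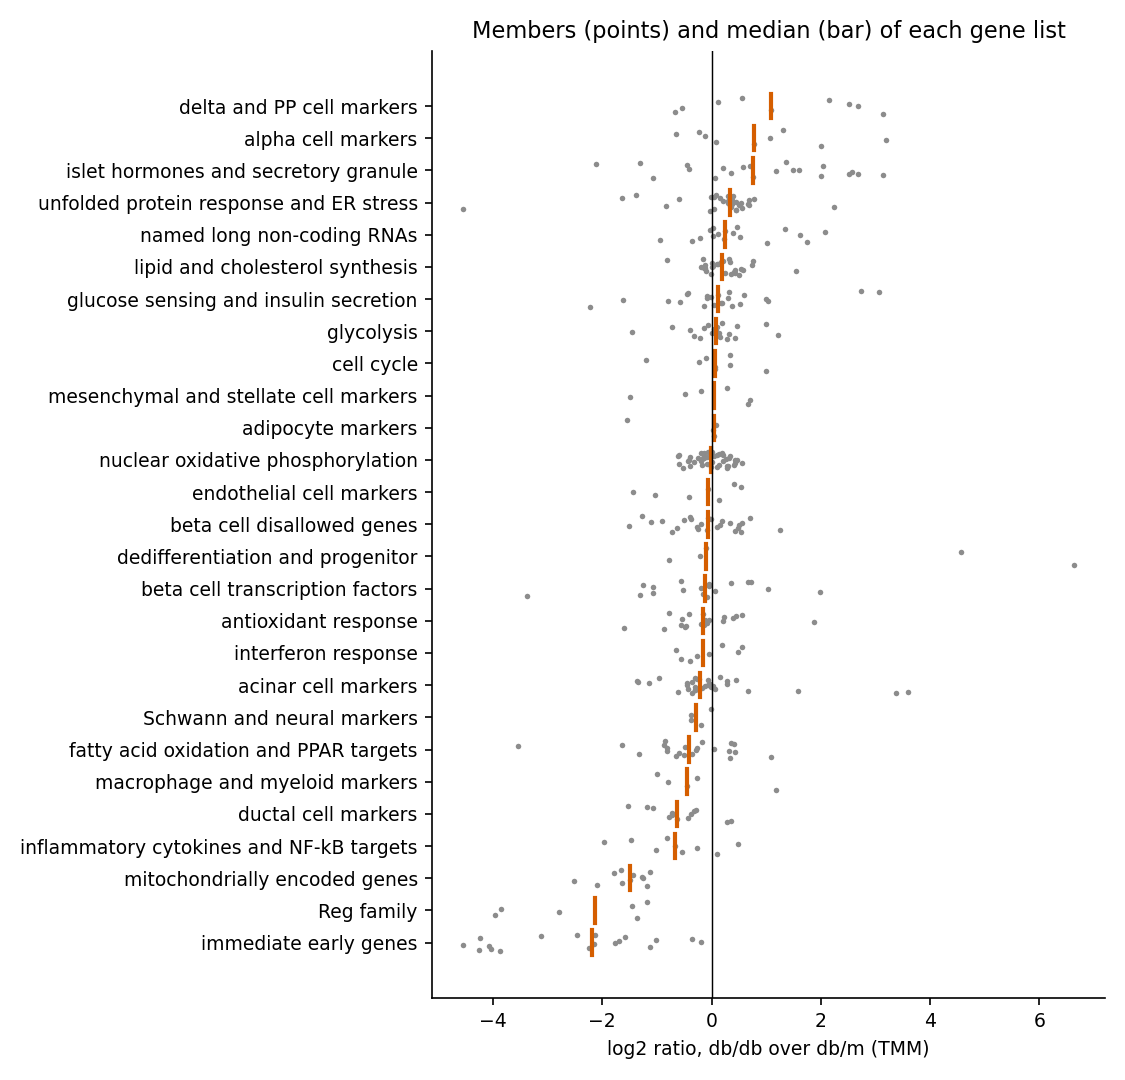
Log2 ratio of db/db over db/m after TMM scaling (x axis) for the measured members (grey points, 1 gene each) and the median (orange bar) of each pathway or cell type list that was fixed beforehand and had at least 4 measured members. Among these lists, immediate early genes lie lowest with a median of -2.19 and delta and PP cell markers highest with 1.09.

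Markers of other cells of the pancreas took small shares of the counts in both libraries. The largest share was that of the ductal markers, with 0.0319% of the db/db counts and 0.041% of the db/m counts. Of 13 ductal markers, 3 were lower in the db/db library (Ambp, Bicc1 and Dcdc2a) and 10 were neither, with a median log2 ratio of -0.64 at percentile 0. The keratin genes Krt8 and Krt18 were 1.55-fold (1.44 to 1.68) and 1.35-fold lower (1.27 to 1.43). Acinar genes made up most of both libraries, and which cells supplied the reads of these ductal markers was not tested. Both measured lymphocyte markers, the immunoglobulin genes Ighm and Igkc, were lower, with a median of -1.31 at percentile 0.71. Of 5 macrophage markers Lyz2, named after its values were seen, was higher (2.28-fold, 1.52 to 3.49) and 4 were neither, with a median of -0.45 at percentile 7.82. Endothelial markers were lower in 2 of 7 cases (Plvap and Kdr), with a median of -0.07 at percentile 37 that was 0.11 with total counts, and mesenchymal markers in 1 of 6 (Acta2), with a median of 0.05 at percentile 55.2 and a mean of -0.08. The 4 Schwann cell markers were neither (median -0.29, percentile 8.78), 1 of 4 adipocyte markers was lower (Lipe, median 0.04, mean -0.34, percentile 55.2), and Bpgm, the 1 measured erythroid marker, was 1.72-fold lower (1.42 to 2.1).

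Long non-coding RNAs were a stated aim of the series. The class marked lncRNA in the table held 7446 genes, of which 1203 had a count and 102 reached a mean of 1 CPM, and together they took 0.0502% of the db/db counts and 0.0484% of the db/m counts. Of the 102, 9 were higher in the db/db library and 12 were lower, while with total counts 13 were higher and 6 lower, so the balance between them depends on the scaling. LOC102638528 was 16.3-fold lower (9.09 to 32.3) and LOC102639290 7.25-fold (3.79 to 15.3), while LOC102636154 was 3.71-fold higher (1.85 to 8.24) and LOC102638489 3.16-fold (1.49 to 7.46). The separate class marked ncRNA, which holds the long non-coding RNAs with an official symbol along with small RNAs, was added after the table was seen and had 24 higher and 16 lower genes among 182. In that class Gm15441 was 9.15-fold lower (7.55 to 11.2), 1110038B12Rik 5.9-fold lower (4.1 to 8.72) and 1700110K17Rik 2.86-fold higher (2.16 to 3.84). The span of 1110038B12Rik on chromosome 17 (34950235 to 34952471) holds Snord52, a 19.6-fold lower gene within 30 kb of Hspa1b. Like the other neighbours of heat shock genes, 1110038B12Rik is uncertain because the strand used in counting is not given. The same limit holds for Gm15441 and the other non-coding RNAs named here wherever their spans overlap another gene, which was not checked for them. Of 17 long non-coding RNAs listed by name, 5 were higher (Airn, Meg3, Rian, Snhg11 and Trp53cor1), 0 were lower and 12 were neither, with a median of 0.24 at percentile 95.2. Airn was 4.22-fold higher (1.74 to 12.3), and the abundant nuclear transcripts Malat1 and Neat1 were 1.28-fold (1.26 to 1.3) and 1.93-fold lower (1.81 to 2.06).

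Other genes at the ends of the ranking belonged to no islet list. Pappa2, a protease that cleaves IGF-binding proteins, was 21.7-fold higher in the db/db library (13 to 39), and the lipid droplet protein gene Plin4 was 8.21-fold higher (6.9 to 9.83). The chromatin remodeller gene Smarca1 was 7.19-fold higher (5.42 to 9.7), the threonine dehydrogenase gene Tdh 6.56-fold (4.89 to 8.95), the kinase gene Nek10 6.43-fold (5.42 to 7.69) and Gas7 5.4-fold (4.29 to 6.87). The complement gene C4b was 16.7-fold lower (11.9 to 24.3), and it has a close copy, C4a, on the same chromosome. C4a was itself 22.1-fold lower, whereas reads moving to it from C4b would have made it higher.

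Checks of the RNA itself gave the following values. Transcripts of the Y chromosome genes Ddx3y (300 and 174 counts), Eif2s3y (321 and 268) and Uty (282 and 205) were present in both libraries, and Xist, named after its values were seen, had 0 counts in the db/db library and 8 in the db/m library. The 4 measured sex-linked genes were neither higher nor lower, with a median of 0.02 and a mean of -0.04 at percentile 49.1. Of 12 histone and other transcripts without a poly(A) tail, 2 were lower (Hist1h1c, 2.4-fold, 1.92 to 3.01, and Hist1h1e) and 10 were neither, with a median of -0.33 at percentile 0.65. The RNA component gene Rmrp was 1.91-fold lower (1.82 to 1.99).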

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

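Chosen only after the results were seen were the class marked ncRNA, the comparison with Ins2, the counts without trypsinogen, immediate early and heat shock genes and the summed islet cell markers without hormone genes. Depth limits genes near 1 CPM, where 1 count stands for 0.0516 CPM in the db/db library and 0.0653 CPM in the db/m library, and the intervals leave out differences between animals, which 1 library per group does not show. No paired analysis was possible because each group has 1 library. The planned change of pseudocount was not run, because the table holds counts.

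Of 31 lists, 15 had a median outside the central 95% of the random lists, and 13 of these kept their sign under every alternative run. The exceptions were alpha cell markers, with a median log2 ratio of -0.0181 without the filter, and antioxidant genes, with 0.0259 under total counts. The named genes included 66 calls, and DESeq2 size factors changed none. Each of the total count scalings lost 3 calls (Arap2, Ins1 and LOC102640618) and gained Vamp2. Lepr stayed without a detectable difference under each scaling. Leaving out the trypsinogen, immediate early and heat shock genes gave 387 higher and 388 lower genes. Leaving out the hormone genes turned the summed alpha cell markers from 1.56-fold to 0.882-fold and moved the delta and PP cell markers from 2.83-fold to 1.25-fold.

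The total number of calls followed the limits by construction, but the balance of higher and lower genes also moved under some limits. Higher genes were 48.7% of calls in the main setting, 27.5% at 10 CPM and 39.3% at the Bonferroni level. They were 49.3% at 1.5-fold and 50.6% at 4-fold. The counts of higher and lower genes were 745 and 814 without a filter, 36 and 95 at a mean of 10 CPM or more, 889 and 914 at 1.5-fold, 78 and 76 at 4-fold, 99 and 137 with the interval beyond 2-fold, and 138 and 213 at the Bonferroni level. Total counts shift every ratio upward and gave 277 lower genes. They turned the balance of lncRNAs from 9 higher and 12 lower to 13 and 6, or 13 and 7 when hormone and acinar genes were left out of the total, while DESeq2 size factors gave 7 and 12. Without a filter 36 lncRNAs were higher and 51 lower, and the class marked ncRNA had 24 higher genes.

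The same shift moved medians under total counts and under totals without hormone and acinar genes to 0.52 and 0.49 for the unfolded protein response, -1.32 and -1.36 for mitochondrially encoded genes, -2.02 and -2.05 for immediate early genes, -1.95 and -1.99 for the Reg family, and -0.0293 and -0.0597 for acinar markers, which were at -0.21 with DESeq2 size factors. Fewer or more members moved the median of the hormone and granule list to 0.70 without a filter, 1.18 at 10 CPM and 0.58 without members of other lists. Leaving out members of other lists gave -2.80 for the Reg family and -0.17 for acinar markers, and the 10 CPM filter gave -2.46 for immediate early genes. Set against counts without acinar markers, the hormone share was 0.83% in the db/db library and 0.646% in the db/m library.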

Other observations

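The genes and lists in this part were chosen after the table was seen. So were the tests of library scaling, the acinar share, the amount of islet tissue, the share of beta cells and the shares of alpha cells and of delta and PP cells, while the tests of a general stress response, shared reads, a haplotype, clock phase and glucocorticoids were set before their values were seen. The conditions under which shared reads and glucocorticoids stay undecided below were not part of those preset tests.

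Single genes of hormone-producing cells, picked by their values, differed in the db/db library. Several of these genes, such as Scg2, Scg3, Scg5, Gc and Kcnk16, are members of lists described above. The genes picked here were not examined as a list of their own. The secretogranin genes Scg2 (2.27-fold, 2.1 to 2.44), Scg3 (2.82-fold, 2.39 to 3.34) and Scg5 (3.02-fold, 2.2 to 4.21) were higher, whereas the prohormone convertase genes Pcsk2, at 1.15-fold (0.989 to 1.35), and Pcsk1, 1.33-fold lower (1.05 to 1.69), were not. Cholecystokinin (Cck) had 32 counts in the db/db library and 0 in the db/m library, at least 8.43-fold higher against a floor of 3 counts, and the granule peptide gene Vgf had 29 counts against 1. Gc, the vitamin D binding protein made by alpha cells, was 9.09-fold higher (4.77 to 19.5), and the potassium channel gene Kcnk16 6.62-fold (3.17 to 16).

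Other single genes outside the lists fixed beforehand also differed. The sterol transporter genes Abcg5 (7.72-fold, 4.36 to 14.9) and Abcg8 (6.29-fold, 4.21 to 9.77), which lie side by side on chromosome 17, were both higher in the db/db library, as was the lipid droplet gene Plin5 (7.27-fold, 2.9 to 23.4). Cps1, the carbamoyl phosphate synthetase of the urea cycle, had 115 counts in the db/db library and 1 in the db/m library. Among clock genes, Dbp was 4.22-fold higher (2.97 to 6.14) and Nr1d1 3.27-fold higher (2.39 to 4.57), whereas Nfil3 was 3.56-fold lower (2.76 to 4.64). The 8 measured genes that peak near Dbp had a median log2 ratio of 0.55, and the 4 that peak opposite to it -0.91. The difference of 1.46 is in line with a shifted clock phase, which may come from the hour at which tissue was taken or from the genotype, and neither was tested.

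Immediate early and heat shock genes were lower in the db/db library. The median of the immediate early list stayed at -2.02 or below under all 4 scalings. Total counts shifted every log2 ratio by only 0.175, so the choice among these scalings could not have removed a median of -2.19. The summed acinar share of the counts differed by 1.007-fold, too little for a different acinar share to account for that median. Both answers followed from values already known, so neither was an independent test. A stress response before lysis that was stronger in the db/m islets, for example during isolation, could also lower these genes in the comparison. The 18 other targets of heat shock factor had a median of -0.41 at percentile 0.02 of the random lists. Only 3 were called lower, although 15 had a ratio below 1. That median lies between the limits set beforehand, so a general stress response cannot be told apart from a difference restricted to the strongest responders. A difference between the genotypes stays open and untested, since each genotype has 1 library.

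The trypsinogen genes of low abundance were higher in the db/db library, and the summed trypsinogen counts, set against the other acinar markers, differed by 1.07-fold, where 8 higher genes made up 5.93% of the sum in the db/db library and 0.517% in the db/m library. That lies below the limit of 1.1-fold set beforehand, under which reads would only have moved between copies. By their own rise, however, the 8 genes were too small a part of the sum to pass that limit. This condition was not set beforehand, and with it the test does not decide. The 4 other copies were at 1.01-fold, without the small loss that reads moving to the 8 genes would leave, but single copies among them ranged from 0.654-fold (Try4) to 1.59-fold (Try5) after TMM scaling, so shared reads cannot be told apart from a difference in expression. The 9 other measured genes within 1 Mb had a median absolute log2 ratio of 0.68 against 0.27 for windows of as many genes, at percentile 98.8. This is consistent with a different haplotype of the region in the db/db mice, although the windows were not matched on expression and both libraries are labelled with the same strain. The genotype itself was not tested.

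Islet genes moved apart between the libraries. More islet tissue in the db/db library would, by itself, raise the hormone genes alike. However, the lower bound for Sst, the highest of the 7, lay 13.7-fold above the upper bound for Ins1, the lowest. These 2 genes were picked by their values, and more islet tissue together with other differences was not tested. A different share of beta cells would, by itself, leave ratios to Ins2 in place. Yet 5 of 5 beta cell genes had an interval excluding 1, with a median ratio of 0.219. A larger share of alpha cells cannot be told apart from higher expression per cell, since 4 of their transcription factors had 8 counts against 2, a ratio of 3.16 (0.631 to 30.6) that may match the 3.99-fold difference of Gcg, while the alpha cell markers without Gcg, at 0.882 (0.838 to 0.93), go against it but had 2715 counts in the db/m library beside 752 for Gcg, so that other cells may supply most of them. A larger share of delta and PP cells cannot be told apart from higher expression per cell either, since the markers of these cells without hormone genes, at 1.25 (1.12 to 1.39) against 8.79 for Sst, had 558 counts in the db/m library beside 211 for Sst, Ppy and Pyy and may likewise come from other cells. A response of islet cells to the db/db genotype stays open as an untested hypothesis.

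A response to glucocorticoids was also examined. Zbtb16 (2.56-fold, 2.19 to 3), Glul (2.65-fold, 2.48 to 2.84) and Plin4 (8.21-fold), which glucocorticoids induce in several tissues, were higher in the db/db library, which could suggest a glucocorticoid response. The 14 other measured targets had a median log2 ratio of -0.17 with 0 called higher and 3 called lower, Cebpd (4.03-fold, 2 to 8.79), Sult1a1 (3.08-fold, 2.39 to 4) and Ddit4 (2.39-fold, 1.81 to 3.17). That median lies below the limit of 0.25 set beforehand, which goes against a shared response. As 7 of the targets lay above 0, with Fkbp5 at 1.58-fold (1.45 to 1.72), short of 2-fold, and 7 below, a median over members that go both ways does not decide, and a glucocorticoid response cannot be told apart from separate causes for these genes. The condition on members that go both ways was not set beforehand, and by the preset limit alone the prediction failed.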
